A study of Homo sapiens with 4 samples.

How the data were processed

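Gene expression was measured by RNA sequencing of poly(A) libraries, 1 per sample, from 4 samples of primary human fibroblast-like synoviocytes: 2 kept without an agent and 2 given NETs, all for 48 h. Per the labels' protocols, the cells came from osteoarthritic or rheumatoid joints, and the libraries were read as single-end 50-base reads on a HiSeq 3000 sequencer. All 4 sample titles carry the same code, which starts with RA. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.1.0, Partek and the human genome build hg19, without the role or order of each.

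The deposited expression table gives RPKM for 27196 genes in 4 columns, and per the file headers it was exported from Partek. It holds small remainders, with 225 to 277 values per library above 0 but under 1e-06 RPKM, so a low value need not be a whole read. A deposited sample sheet gives the alignments per library, from 46633735 to 59442704. The deposited comparison table holds group means that equal log2(RPKM + 0.1) within 0.001 for 27195 genes. Per the file headers it also gives a p-value, a q-value and a ratio per gene. Its signed fold change is a score the authors deposited, the ratio where at least 1 and otherwise minus the inverse of the ratio. Its p-values lay within 1% of an analysis of variance with 2 residual degrees of freedom for 20730 of 20732 genes compared, and 6463 genes carried no p-value. Gene types and locations in cells are annotation columns of the deposited table. Whole reads were sought in 5879 low values, and 46.8% were whole multiples within 0.02, where chance gives 4%. Read counts were therefore not recovered, and count models were not run. The depth behind a single gene's value is thus unknown, and no counting interval is given.

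What was computed here began from RPKM as deposited. Values were moved to log2(RPKM + 0.5), and genes with a mean of at least 1 RPKM over the 4 libraries were kept, which left 11350. limma 3.58.1 in R 4.3.3 fitted the 2 groups with no block (lmFit, and eBayes with an intensity trend, prior degrees of freedom 9.63 beside 2 residual ones), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 26 lists with a tested member, and again with an estimated correlation and with fry. The 27 lists, 22 on biology and 5 on markers of other cell types, were fixed before the data were examined, and so were the main design and the other settings tried. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Gene names, neighbours and transcript lengths came from GENCODE and RefSeq annotation of GRCh38, a later build than that of the files, so no coordinates are given.

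The genes named were the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, the 2 members with the lowest p of each biology list, the 3 members with the highest mean of each marker list, and 14 genes chosen for the topic (PADI2, PADI4, HLA-DRA, HLA-DRB1, CD74, CIITA, IL6, CXCL8, MMP1, MMP3, ACAN, PRG4, AGER and TLR9). Some genes that this rule selects are not reported here. Other genes given as examples were chosen after their values were seen, and were refitted under 12 of the settings below. Levels of sex-linked transcripts are not reported here.

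The fit was tested on simulated data for the comparison of NETs with no agent, with 11350 genes of which 200 were changed. It recovered 11.9% of the genes changed by 0.5 on the log2 scale, 67.2% of those changed by 1 and 92.4% of those changed by 2, with 5 false calls among 119, and 2 of 100 unchanged gene sets had p under 0.05. Simulated genes varied independently, so these sets do not speak for lists of correlated genes. Their spreads were shuffled over genes, and far fewer genes were changed than were called in the data. The rates need not carry over. Alternatives varied the pseudocount, the filter, the scaling, the intensity trend, the threshold, a replicate block, each library left out, the list test and the authors' own comparison. Without the filter, fold changes stay the same but the prior degrees of freedom fall to 1.68. That weakens the test of abundant genes too.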

Results

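RNA was measured by poly(A) RNA sequencing in primary human fibroblast-like synoviocytes, the fibroblasts of the joint lining, 48 h after neutrophil extracellular traps (NETs) were added or no agent was given. NETs are webs of chromatin and granule proteins that neutrophils release. Each of the 2 groups held 2 libraries, and the file headers give all 4 libraries 1 and the same cell code, while the sample titles share a code that starts with RA. The spread between replicates is thus that within 1 cell source, and the labels do not say whether replicates were separate cultures. The files give 52992207 and 47090216 alignments for the no agent libraries and 59442704 and 46633735 for the NETs libraries. Between 11214 and 11294 genes per library had at least 1 RPKM (reads per kilobase of transcript, scaled to the mapped reads of the library). Below, log2FC is the log2 fold change, NETs against no agent. Over the tested genes, log2 values correlated across genes at r = 0.995 between the no agent replicates and at r = 0.992 between the NETs replicates, against 0.924 to 0.929 between groups, where genes are not independent replicates.

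The only comparison in the design asks which genes of synovial fibroblasts change with NETs, in a study on NETs and cartilage damage in rheumatoid arthritis. Fibroblasts given NETs held far more RNA for chemokines that attract neutrophils and for inflammatory cytokines. CXCL8 rose from 1.01 ± 8.41e-04 to 2523 ± 209 RPKM (SD, n = 2 each), a log2FC of 10.71 ± 0.11 (SE, limma adjusted p = 1.71e-14). CXCL6 rose from 3.9 ± 0.0299 to 7103 ± 246 RPKM (SD, n = 2 each), a log2FC of 10.66 ± 0.11 (SE, limma adjusted p = 1.71e-14), and became the most abundant of the tested cytokine genes. The matrix protease MMP3, stromelysin, rose from 1.28 ± 0.167 to 1111 ± 13.5 RPKM (SD, n = 2 each), a log2FC of 9.29 ± 0.11 (SE, limma adjusted p = 3.11e-14). The other largest rises were the chemokines CXCL1 (1.95 to 1942 RPKM, log2FC 9.63 ± 0.11 SE) and CXCL3 (0.498 to 439.6 RPKM, log2FC 8.79 ± 0.10 SE). CXCL5 (0.0901 to 182 RPKM, log2FC 8.27 ± 0.10 SE) followed. CXCL1, CXCL2 and CXCL3 are near-identical genes between which short reads can be shared. The largest falls were the neuronal pentraxin NPTX1 (80 to 1.46 RPKM, log2FC -5.36 ± 0.10 SE) and the urea transporter SLC14A1 (28.5 to 0.788 RPKM, log2FC -4.49 ± 0.10 SE). The small leucine-rich proteoglycan ASPN (22.9 to 1.54 RPKM, log2FC -3.52 ± 0.11 SE) and the alcohol dehydrogenase ADH1B (5.79 to 0.133 RPKM, log2FC -3.32 ± 0.12 SE) fell as well. The basement membrane zone collagen COL15A1 (72.5 to 8.38 RPKM, log2FC -3.05 ± 0.12 SE) and the tubulin TUBB3 (107 to 13.6 RPKM, log2FC -2.93 ± 0.10 SE) came next. The order of these genes rests on the pseudocount. At pseudocount 0.1, CXCL5 (log2FC 9.90) lay above CXCL1 (9.89), MMP3 (9.66), C15orf48 (9.64) and CXCL3 (9.52), ADH1B (-4.69) lay beyond ASPN (-3.81), and COL15A1 and TUBB3 were not among the 8 largest falls. At pseudocount 1, CXCL6 (10.50) lay above CXCL8 (10.29).

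limma with Benjamini-Hochberg adjustment tested 11350 genes and called 4391, of which 1556 were higher and 2835 lower with NETs. At least a 2-fold change was seen for 362 higher and 397 lower genes, and at least an 8-fold change for 59 higher and 5 lower. The genes at least 8-fold higher took 0.105% and 0.102% of summed RPKM in the no agent libraries and 7.04% and 7.22% in the NETs libraries. With median of ratios scaling in place of the deposited scale, 2039 genes were higher and 2121 lower, so the split of 35.4% higher became 49.0%. The median log2FC over all tested genes was -0.09 on the deposited scale. The list test fry does not take this shift off. The groups did not overlap for 69.1% of tested genes, where chance gives 33.3%. Fold changes are on the log2(RPKM + 0.5) scale, which understates the change of low genes, and all p-values rest on the spread between libraries of 1 cell source.

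**Figure D1:**
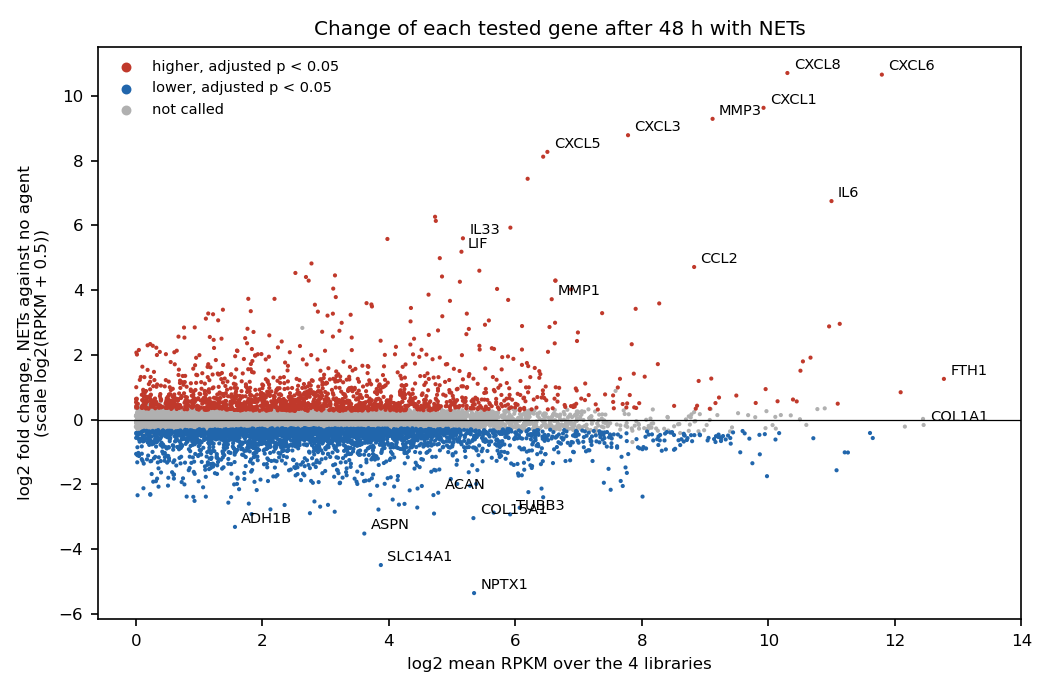
Log2 fold change with NETs (y axis, scale log2(RPKM + 0.5)) against log2 mean RPKM (x axis) for each tested gene, coloured by whether it was higher, lower or not called at an adjusted p under 0.05. CXCL8 at 10.71 and CXCL6 at 10.66 lie at the top and NPTX1 at -5.36 at the bottom.

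Most tested cytokine and chemokine genes rose, though the filter on the mean of all 4 libraries also admits genes that are above it only with NETs. Of 23 tested members (34 listed), 22 rose, 0 fell and 1 did not pass, and adjusted over the list alone 22 rose and 0 fell. Cytokines and chemokines had a median log2FC of 4.71 with limma's camera adjusted p = 9.93e-36, and adjusted p = 0.130 with an estimated correlation. IL6 (37.1 to 4055 RPKM, log2FC 6.75 ± 0.13 SE) rose. The monocyte chemokine CCL2 (32.9 to 876 RPKM, log2FC 4.71) and the alarmin IL33 (0.980 to 71.1 RPKM, log2FC 5.60) rose as well. IL1B (0.127 to 12.8 RPKM, log2FC 4.40) and CSF3 (0.0177 to 11.5 RPKM, log2FC 4.53) rose from near 0. CCL20 was listed at 0 in both no agent libraries and at 12.4 and 15 RPKM in the NETs libraries. CXCL12 was the tested member that did not pass, at 47.5 and 50.3 RPKM. TNF stayed under the filter, at 0 and 0.00262 RPKM, and so did the interferon-induced chemokine CXCL10, at 0 and 0.00937 RPKM.

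Targets of NF-kB, the transcription factor of inflammatory signalling, and adhesion genes mostly rose. Of 22 tested members (25 listed), 19 rose, 1 fell and 2 did not pass, and adjusted over the list alone 19 rose and 2 fell. NF-kB targets and adhesion had a median log2FC of 1.29 with limma's camera adjusted p = 2.74e-15, and adjusted p = 0.156 with an estimated correlation. The prostaglandin enzymes PTGS2 (2.1 to 55.2 RPKM, log2FC 4.42 ± 0.10 SE) and PTGES (2.95 to 83.3 RPKM, log2FC 4.6 ± 0.11 SE) had the lowest p in the list. The mitochondrial superoxide dismutase SOD2 (47.2 to 572 RPKM, log2FC 3.59) and the hyaluronan-binding TNFAIP6 (30.3 to 301 RPKM, log2FC 3.29) also rose. TNFAIP3 (6.0 to 36.2 RPKM, log2FC 2.50) and NFKBIA (22.8 to 88.1 RPKM, log2FC 1.93), inhibitors of NF-kB signalling, rose too. ICAM1 (4.88 to 13.1 RPKM, log2FC 1.35) rose and VCAM1 (29.3 to 19.4 RPKM, log2FC -0.58) fell.

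**Figure D2:**
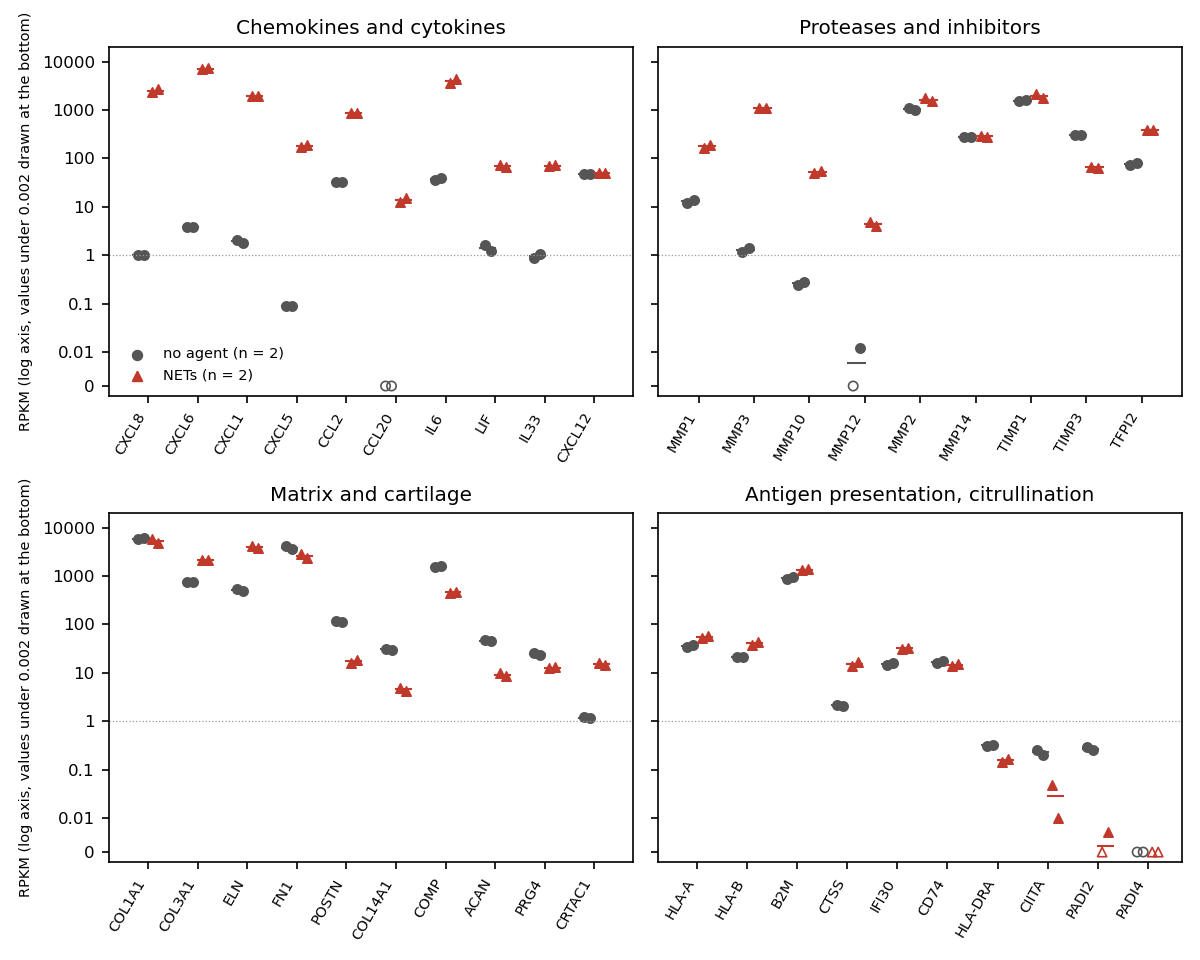
RPKM in each library of 39 genes chosen after their values were seen (log axis, points are libraries, short lines are group means, open symbols are values of 0), for no agent and NETs libraries (n = 2 each). IL6 goes from 37.1 to 4055 RPKM and MMP3 from 1.28 to 1111 RPKM, while PADI4 is listed at 0 in all 4 libraries.

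Among genes of proteases that degrade matrix, collagenase and stromelysins rose. Of 25 tested members (33 listed), 12 rose, 5 fell and 8 did not pass, and adjusted over the list alone 13 rose and 6 fell. Matrix-degrading proteases had a median log2FC of 0.28 with limma's camera adjusted p = 5.82e-05, and adjusted p = 0.205 with an estimated correlation. The median was 0.15 without the filter on low values and between 0.18 and 0.35 over left-out libraries. The interstitial collagenase MMP1 (13 to 178 RPKM, log2FC 3.72 ± 0.11 SE) and MMP10 (0.264 to 53.3 RPKM, log2FC 6.14 ± 0.10 SE) rose with MMP3. The gelatinase MMP2 (1057 to 1627 RPKM, log2FC 0.62) and ADAM12 (22.9 to 69.2 RPKM, log2FC 1.58) rose too. The membrane protease MMP14 did not pass, at 278 and 284 RPKM. The cathepsins split, since CTSS (2.14 to 15.2 RPKM, log2FC 2.56) rose while CTSB (545 to 343 RPKM, log2FC -0.67) and CTSL (480.2 to 258 RPKM, log2FC -0.90) fell. Without the filter on low values MMP2 and CTSL were not called, at limma adjusted p of 0.120 and 0.0970, nor was MMP2 under quantile normalization, at 0.131. MMP13, the collagenase of cartilage, stayed under the filter at 0.128 and 0.696 RPKM, and was called higher without the filter (adjusted p = 0.0266).

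Genes of protease inhibitors moved in both directions. Of 18 tested members (20 listed), 8 rose, 4 fell and 6 did not pass, and adjusted over the list alone 9 rose and 4 fell. Protease inhibitors had a median log2FC of 0.18 with limma's camera adjusted p = 0.00807, and adjusted p = 0.313 with an estimated correlation. The elastase inhibitors SERPINA1 (5.27 to 52.2 RPKM, log2FC 3.19 ± 0.10 SE) and PI3 (0.140 to 4.79 RPKM, log2FC 3.07) rose, and so did TFPI2 (75.9 to 382 RPKM, log2FC 2.33 ± 0.11 SE). The metalloprotease inhibitor TIMP3 (298 to 65.9 RPKM, log2FC -2.17) fell, and TIMP1 did not pass, at 1555 and 1950.5 RPKM. TIMP1 was called higher under median of ratios scaling (limma adjusted p = 0.0261) and without the intensity trend (0.0433), and turned downward, not called, under quantile normalization (0.180). Without the filter on low values the list was no longer called, at an adjusted p = 0.116.

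Fibrillar matrix genes split by member and were not called as a list by camera. Of 29 tested members, 7 rose, 14 fell and 8 did not pass, and adjusted over the list alone 7 rose and 14 fell. Fibrillar matrix and its crosslinking had a median log2FC of -0.28 (camera adjusted p = 0.594, fry adjusted p = 0.146). POSTN (117 to 17.3 RPKM, log2FC -2.72 ± 0.11 SE), periostin, and COL14A1 (31.1 to 4.62 RPKM, log2FC -2.63 ± 0.10 SE) fell. COL6A3 (1235 to 485 RPKM, log2FC -1.35) and FN1 (3842 to 2592 RPKM, log2FC -0.57) fell too, though FN1 was not called without the filter on low values or without NETs replicate 2, at limma adjusted p of 0.311 and 0.167. Elastin, ELN (511 to 3969 RPKM, log2FC 2.96), and COL3A1 (757 to 2155 RPKM, log2FC 1.51) rose. COL1A1 did not pass, at 5927 and 5307 RPKM, but was called lower under quantile normalization (log2FC -0.65, adjusted p = 0.00143). Cartilage matrix genes split as well. Of 13 tested members (29 listed), 5 rose, 6 fell and 2 did not pass, and adjusted over the list alone 5 rose and 6 fell. The proteoglycan aggrecan, ACAN (45.8 to 9.18 RPKM, log2FC -2.26 ± 0.11 SE), and the joint lubricant PRG4 (24.4 to 12.7 RPKM, log2FC -0.91 ± 0.11 SE) fell. COMP (1556 to 463 RPKM, log2FC -1.75) fell too. CRTAC1 (1.19 to 15.2 RPKM, log2FC 3.21 ± 0.10 SE) and the hyaluronan synthase HAS1 (0.862 to 7.77 RPKM, log2FC 2.60 ± 0.11 SE) rose. The median of the cartilage list was 0.08 and its mean -0.03, while camera put it upward at an adjusted p = 0.675 (fry adjusted p = 0.861). The chondrocyte collagen COL2A1 was under the filter at 0.00196 and 0.0128 RPKM.

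Genes that mark synovial fibroblasts mostly fell. Of 19 tested members (20 listed), 5 rose, 14 fell and 0 did not pass, and adjusted over the list alone 5 rose and 14 fell. Synovial fibroblast identity had a median log2FC of -0.70 with limma's camera adjusted p = 0.0432, and adjusted p = 0.313 with an estimated correlation. Without NETs replicate 1 and without NETs replicate 2 the list was not called, at an adjusted p = 0.0622 and 0.0619. The stromal markers CD248 (321 to 85.6 RPKM, log2FC -1.90 ± 0.11 SE) and THY1 (91.5 to 34.3 RPKM, log2FC -1.40) fell. FAP (84.1 to 164 RPKM, log2FC 0.96) and PDPN (52.5 to 94.6 RPKM, log2FC 0.84) rose, and so did HAS1. Contractile and TGF-beta response genes were called as a list by fry but not by camera. Of 21 tested members (24 listed), 7 rose, 5 fell and 9 did not pass, and adjusted over the list alone 7 rose and 5 fell. Contractile and TGF-beta response had a median log2FC of 0.01 (camera adjusted p = 0.132, fry adjusted p = 0.00369). Without no agent replicate 1 camera called it too, at an adjusted p = 0.0405. The activin subunit INHBA (6.61 to 43 RPKM, log2FC 2.61 ± 0.11 SE) rose. IGFBP3 (3234 to 1092 RPKM, log2FC -1.57) fell.

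MHC class I presentation genes rose in part. Of 16 tested members (19 listed), 9 rose, 0 fell and 7 did not pass, and adjusted over the list alone 10 rose and 0 fell. MHC class I presentation had a median log2FC of 0.33 with limma's camera adjusted p = 2.77e-04, and adjusted p = 0.348 with an estimated correlation. HLA-B (21.3 to 40.8 RPKM, log2FC 0.91 ± 0.11 SE) and HLA-C (14.1 to 23.1 RPKM, log2FC 0.69 ± 0.11 SE) rose, which share reads with near-identical copies. B2M (915 to 1352 RPKM, log2FC 0.56) rose too, though without the filter on low values it was not called (limma adjusted p = 0.118). Of the MHC class II list, 11 of 16 members were under the filter, and the others were tested. Of 5 tested members (16 listed), 3 rose, 0 fell and 2 did not pass, and adjusted over the list alone 4 rose and 1 fell. MHC class II presentation had a median log2FC of 0.32 with limma's camera adjusted p = 0.00807, and adjusted p = 0.313 with an estimated correlation. The members that rose were CTSS (2.14 to 15.2 RPKM, log2FC 2.56 ± 0.11 SE) and IFI30 (15.1 to 32.1 RPKM, log2FC 1.07 ± 0.10 SE), lysosomal processing enzymes, and RFX5 (log2FC 0.32), a promoter factor. RFX5 was not called without the filter (0.0524) or without no agent replicate 1 or no agent replicate 2 (limma adjusted p = 0.0655 and 0.127). The class II genes themselves were low, HLA-DRA at 0.320 and 0.158 RPKM and HLA-DRB1 at 0.0357 and 0.0224 RPKM. Their regulator CIITA stood at 0.229 and 0.0292 RPKM. Without the filter HLA-DRA and CIITA were called lower, against the direction of the list, at limma adjusted p of 0.0326 and 0.0286. The invariant chain CD74 did not pass, with a log2 fold change of -0.25 ± 0.11 (SE, limma adjusted p = 0.0888), which became 0.0441 without NETs replicate 2. Without the filter the class II list was not called, at an adjusted p = 0.910. The citrullinating enzymes, whose genes were all under the filter, included PADI2 at 0.273 and 0.00261 RPKM, called lower without the filter (adjusted p = 0.00804), and PADI4, listed at 0 in all 4 libraries.

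Interferon response genes were called as a list by fry, downward, but not by camera. Of 26 tested members (36 listed), 4 rose, 10 fell and 12 did not pass, and adjusted over the list alone 5 rose and 11 fell. Type I interferon response had a median log2FC of -0.20 (camera adjusted p = 0.329, fry adjusted p = 0.0266), and of -0.11 under median of ratios scaling. IFIT1 (2.14 to 0.425 RPKM, log2FC -1.51 ± 0.13 SE) and IFIT3 (7.13 to 3.48 RPKM, log2FC -0.94) fell. IFI44L (0.852 to 3.03 RPKM, log2FC 1.38 ± 0.12 SE) rose. Genes that sense nucleic acids or act through RAGE and Toll-like receptors were likewise called downward by fry only. Of 17 tested members (29 listed), 1 rose, 7 fell and 9 did not pass, and adjusted over the list alone 2 rose and 7 fell. Nucleic acid, RAGE and Toll-like sensing had a median log2FC of -0.24 (camera adjusted p = 0.223, fry adjusted p = 0.00469), and of -0.17 under median of ratios scaling. The DNA-sensing adaptor STING, TMEM173 (41.1 to 20.2 RPKM, log2FC -1.0 ± 0.11 SE), and IFI16 (48.6 to 26.6 RPKM, log2FC -0.86 ± 0.11 SE) fell. TLR4 (4.82 to 3.08 RPKM, log2FC -0.57) fell too. RAGE itself (AGER) was under the filter at 0.143 and 0.150 RPKM, and so was TLR9 at 0.130 and 0.0901 RPKM.

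Cell cycle genes mostly rose. Of 32 tested members, 23 rose, 0 fell and 9 did not pass, and adjusted over the list alone 25 rose and 1 fell. Cell cycle had a median log2FC of 0.79 with limma's camera adjusted p = 1.12e-13, and adjusted p = 0.205 with an estimated correlation. RRM2 (5.35 to 16.8 RPKM, log2FC 1.57 ± 0.10 SE) and UBE2C (4.82 to 13.6 RPKM, log2FC 1.40 ± 0.10 SE) rose. MCM2 to MCM7 did not pass, but MCM2 was called higher under median of ratios scaling and quantile normalization (limma adjusted p = 0.0207 and 0.0250). Hypoxia and glycolysis genes mostly rose as well. Of 22 tested members (23 listed), 16 rose, 1 fell and 5 did not pass, and adjusted over the list alone 16 rose and 1 fell. Hypoxia and glycolysis had a median log2FC of 0.70 with limma's camera adjusted p = 3.56e-09, and adjusted p = 0.205 with an estimated correlation. PFKFB3 (2.28 to 8.31 RPKM, log2FC 1.66 ± 0.10 SE), a regulator of glycolysis, and the carbonic anhydrase CA9 (0.0540 to 2.22 RPKM, log2FC 2.29 ± 0.14 SE) rose. The hexokinase HK1 (37 to 25.7 RPKM, log2FC -0.52) fell. Unfolded protein response genes moved in both directions. Of 21 tested members, 11 rose, 6 fell and 4 did not pass, and adjusted over the list alone 11 rose and 6 fell. Unfolded protein response had a median log2FC of 0.37 with limma's camera adjusted p = 0.00946, and adjusted p = 0.313 with an estimated correlation. The median lay between 0.24 and 0.45 over left-out libraries. HYOU1 (26.7 to 58 RPKM, log2FC 1.10 ± 0.11 SE) and ATF3 (1.74 to 4.23 RPKM, log2FC 1.08 ± 0.11 SE) rose. TRIB3 (17.8 to 9.09 RPKM, log2FC -0.95) and DDIT3 (28.2 to 19.4 RPKM, log2FC -0.53) fell, DDIT3 not called without the filter on low values (limma adjusted p = 0.0536). Without NETs replicate 1 and without NETs replicate 2 the list was not called, at an adjusted p = 0.0981 and 0.0746.

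The oxidative stress list was not called as a whole by camera or fry. Of 21 tested members, 5 rose, 13 fell and 3 did not pass, and adjusted over the list alone 5 rose and 13 fell. Oxidative stress response had a median log2FC of -0.51 (camera adjusted p = 0.168, fry adjusted p = 0.0770). Without the filter its adjusted p was 0.0336. The metal-binding metallothioneins MT2A (477 to 3509.6 RPKM, log2FC 2.88 ± 0.13 SE) and MT1E (33.6 to 221 RPKM, log2FC 2.69 ± 0.14 SE) rose, and so did the ferritin heavy chain FTH1 (4143 to 9886 RPKM, log2FC 1.26), which was not called without the filter (limma adjusted p = 0.150). NQO1 (106 to 31.7 RPKM, log2FC -1.72) and HMOX1 (187 to 97.1 RPKM, log2FC -0.95) fell. Genes of p53 targets and apoptosis were called as a list by fry, downward, but not by camera. Of 20 tested members (21 listed), 4 rose, 9 fell and 7 did not pass, and adjusted over the list alone 5 rose and 9 fell. p53 response and apoptosis had a median log2FC of -0.20 (camera adjusted p = 0.361, fry adjusted p = 0.0133), and of -0.12 under median of ratios scaling. ZMAT3 (14.2 to 6.54 RPKM, log2FC -1.06 ± 0.10 SE) and TP53INP1 (6.02 to 2.69 RPKM, log2FC -1.03 ± 0.10 SE) fell. The cell cycle inhibitor CDKN1A (142 to 85.9 RPKM, log2FC -0.72) fell too. Most tested cholesterol synthesis genes fell. Of 21 tested members (22 listed), 2 rose, 14 fell and 5 did not pass, and adjusted over the list alone 2 rose and 15 fell. Cholesterol synthesis had a median log2FC of -0.39 with limma's camera adjusted p = 0.00658, and adjusted p = 0.348 with an estimated correlation. The falls included MSMO1 (18.7 to 7.68 RPKM, log2FC -1.23 ± 0.10 SE). The rises called were LSS (13.8 to 18.1 RPKM, log2FC 0.37) and STARD4 (1.46 to 1.95 RPKM, log2FC 0.32), both lost without the filter (limma adjusted p = 0.0758 and 0.0956). LSS was also lost when any library but NETs replicate 2 was left out (0.0577 to 0.0881), and STARD4 when any library was (0.0714 to 0.183). Lysosome and uptake genes were called downward by fry but not by camera. Of 24 tested members (25 listed), 2 rose, 10 fell and 12 did not pass, and adjusted over the list alone 2 rose and 10 fell. Lysosome and uptake had a median log2FC of -0.18 (camera adjusted p = 0.466, fry adjusted p = 0.0401), and of -0.09 under median of ratios scaling. CAV1 (148 to 85.5 RPKM, log2FC -0.79 ± 0.11 SE) and NPC1 (18.4 to 11.7 RPKM, log2FC -0.63 ± 0.10 SE) fell.

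Genes of cytosolic ribosomal proteins fell by a small amount. Of 28 tested members, 0 rose, 20 fell and 8 did not pass, and adjusted over the list alone 0 rose and 24 fell. Cytosolic ribosomal proteins had a median log2FC of -0.46 with limma's camera adjusted p = 2.56e-04, and adjusted p = 0.554 with an estimated correlation. RPL3 (777 to 507 RPKM, log2FC -0.61 ± 0.12 SE) was among the members that fell, though without the filter on low values it was not called (limma adjusted p = 0.0635). Between the no agent replicates the list's median log2 difference was 0.24, and without NETs replicate 1 and without NETs replicate 2 the list was not called, at an adjusted p = 0.0921 and 0.0746, nor was it by fry, at 0.0770. Oxidative phosphorylation genes were not called. Of 24 tested members, 1 rose, 1 fell and 22 did not pass, and adjusted over the list alone 0 rose and 0 fell. Their median log2FC was -0.09, beside -0.09 over all tested genes, while camera put the list upward at an adjusted p = 0.675 and fry downward at 0.832. NDUFA4 (48.4 to 37.7 RPKM, log2FC -0.36 ± 0.11 SE) fell and ATP5B (141 to 175 RPKM, log2FC 0.31 ± 0.11 SE) rose with all 4 libraries. ATP5B was not called when any 1 library was left out, at limma adjusted p from 0.111 to 0.172. Nor was NDUFA4 without no agent replicate 2 or without NETs replicate 1, at adjusted p of 0.225 and 0.0851, or under median of ratios scaling, at 0.0770. Without the filter neither was called, at adjusted p of 0.0641 for ATP5B and 0.0946 for NDUFA4.

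**Figure D3:**
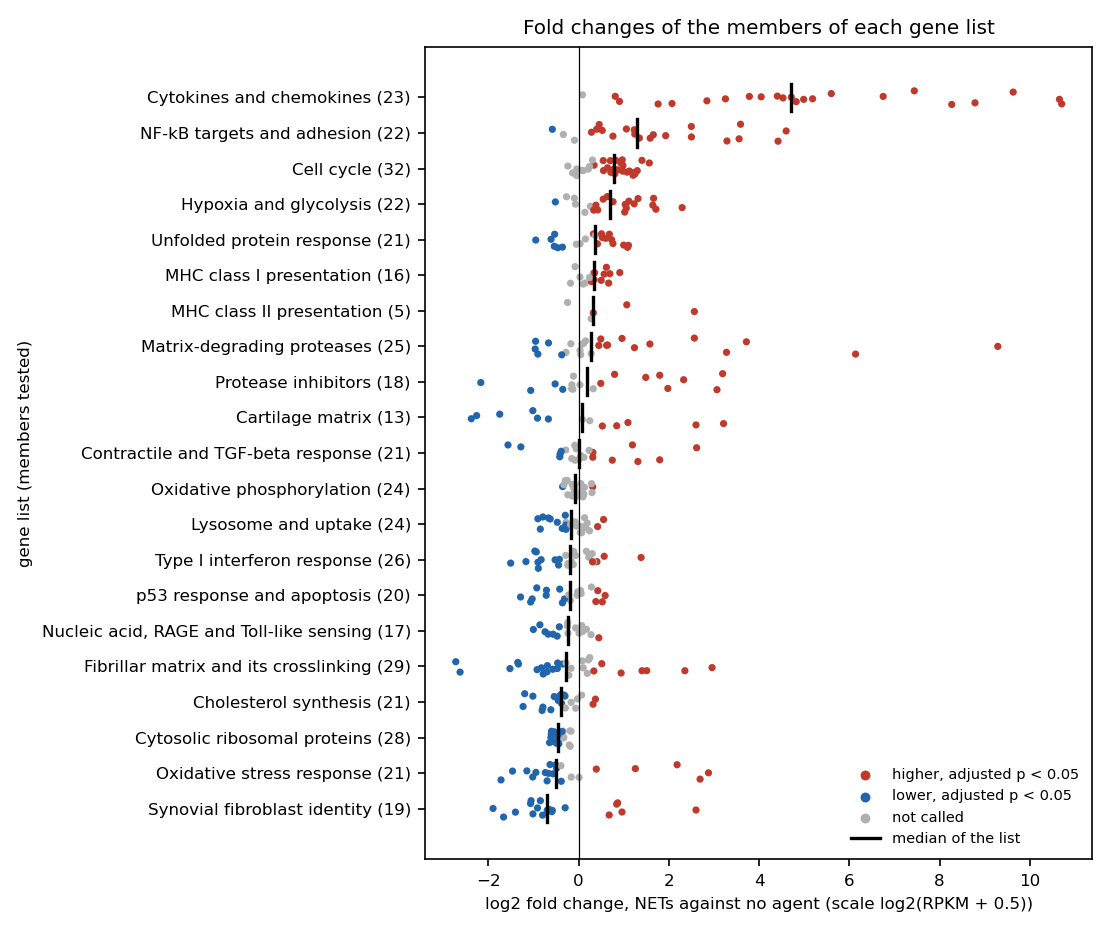
Log2 fold change with NETs of each tested member (points, scale log2(RPKM + 0.5)) of the 21 biology lists that had tested members, coloured by call, with the median of each list as a black line. The cytokine list has the highest median, 4.71, and the synovial fibroblast identity list the lowest, -0.70.

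Most markers of other cell types were under the filter. Of 30 neutrophil markers 27 were under the filter, and the genes MPO, ELANE and S100A8 stood at 0.00709, 0.396 and 0.0280 RPKM with NETs. Of 3 tested members (30 listed), 2 rose, 0 fell and 1 did not pass, and adjusted over the list alone 2 rose and 0 fell. Neutrophil markers had a median log2FC of 1.55 with limma's camera adjusted p = 0.00905, and adjusted p = 0.313 with an estimated correlation. SRGN (27.8 to 82.4 RPKM, log2FC 1.55 ± 0.11 SE) and G0S2 (10.8 to 40.9 RPKM, log2FC 1.86 ± 0.11 SE) rose. ITGB2 stood at 11.6 and 11.3 RPKM. CD68 was the macrophage marker above the filter. Of that 1 gene, 0 rose, 0 fell and 1 did not pass, and adjusted over the list alone 0 rose and 0 fell. Macrophage markers had a median log2FC of 0.16 (camera adjusted p = 0.534, fry adjusted p = 0.209). CD68 stood at 117 and 130.4 RPKM without and with NETs, CD14 at 0.650 and 0.576 and FCER1G at 0.343 and 0.742. IL7R was the lymphocyte marker tested. Of that 1 gene, 1 rose, 0 fell and 0 did not pass, and adjusted over the list alone 1 rose and 0 fell. Lymphocyte markers had a median log2FC of 2.13 with limma's camera adjusted p = 0.0194, and adjusted p = 0.313 with an estimated correlation. IL7R (0.269 to 2.86 RPKM, log2FC 2.13 ± 0.12 SE) rose. CD79B stood at 0.157 and 0.0210 RPKM and CD79A at 0.0756 and 0.00710, both called lower without the filter (limma adjusted p = 0.0397 and 0.0325). Without the filter on low values the neutrophil and lymphocyte lists were not called, at adjusted p of 0.243 and 0.967. Endothelial markers above the filter were few, and fry but not camera called the list. Of 3 tested members (13 listed), 1 rose, 2 fell and 0 did not pass, and adjusted over the list alone 1 rose and 2 fell. Endothelial markers had a median log2FC of -0.61 (camera adjusted p = 0.361, fry adjusted p = 0.0133). ERG (12.2 to 3.73 RPKM, log2FC -1.59) and TEK (5.33 to 3.32 RPKM, log2FC -0.61) fell and EGFL7 (0.764 to 1.58 RPKM, log2FC 0.74) rose. PPARG was the adipocyte marker tested. Of that 1 gene, 0 rose, 1 fell and 0 did not pass, and adjusted over the list alone 0 rose and 1 fell. Adipocyte markers had a median log2FC of -0.86 (camera adjusted p = 0.329, fry adjusted p = 0.104). PPARG (1.44 to 0.591 RPKM, log2FC -0.86) fell. Without the filter EGFL7 and PPARG were not called, at limma adjusted p of 0.0900 and 0.0871. CEBPA stood at 0.384 and 0.315 RPKM and PLIN4 at 0.142 and 0.125.

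The authors' deposited comparison, an analysis of variance per gene without pooling of the spread, called 1790 genes at q under 0.05, of which 732 were higher and 1058 lower. Of these, 1356 were tested here and 1269 were called here in the same direction and 0 in the opposite direction, both sets of calls coming from the same 4 libraries. Of the 26 lists with a tested member, 14 were called by camera with the preset correlation and 0 with an estimated one, for which 5 had an unadjusted p under 0.05, and fry, which asks whether members changed and not whether they changed more than other genes, called 19 for a shift on balance and 22 for change in either direction.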

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

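All alternatives here were planned before the data were examined. The number of called genes lay between 3243 and 4601 when 1 library was left out, a fit in which the lone sample is assumed to vary like the other group, with 1282 to 1562 higher and 1939 to 3039 lower. It was 2850, with 954 higher, at a mean RPKM of at least 5, where fewer genes were tested, and 759 (362 higher, 397 lower) when an absolute log2 fold change of at least 1 was also asked for. Without the filter it was 3165 (1253 higher, 1912 lower), and only 2428 of the 4391 calls (55.3%) were kept, against 63.2% at that higher filter, 83.7% under median of ratios scaling and 70.7% to 87.8% with 1 library left out. Without the filter the prior degrees of freedom were 1.68 in place of 9.63, so a lost call there need not reflect low values of that gene. The prior degrees of freedom went the other way, to between 38.2 and 2529, with 1 library left out, and to 32.4 with the replicate block. Stronger pooling of the spread between genes can ease calls in those fits. Their counts and kept calls are thus weak evidence that the results hold. The authors' deposited table gave 1790 (732 higher, 1058 lower) from a test that does not pool the spread between genes. The labels tie same-numbered libraries by number only, and whether they were paired cannot be told. Their deviations from the group means correlated at 0.192, which is a single comparison, since both of the 2 pairs give the same value. The replicate block raised the calls to 5645 (1972 higher, 3673 lower) with all 4391 calls kept. Of the 14 lists called, 0 were called with the estimated correlation. A correlation above the preset 0.01 was argued against as the cause for some lists. Among them were the cytokine and NF-kB lists, with estimates of -0.02 and -0.04. For others the estimate was above the preset, such as 0.21 for MHC class I and 0.74 for ribosomal proteins. What else differs between the 2 versions of the test was not tested. The cartilage list, not called, turned downward without the filter (adjusted p = 0.732) and without NETs replicate 1 (0.892, 0.591 to 0.918 over left-out libraries), and the oxidative phosphorylation list without no agent replicate 1 (0.591), without NETs replicate 2 (0.856) and by fry (0.832), at 0.312 to 0.856 over left-out libraries. ITGB2, not called, turned to 0.0619 under median of ratios scaling and to 0.0404 under quantile normalization, and lay between -0.10 and 0.0438 over left-out libraries. Over all settings, named genes kept direction and side of the threshold in 734 cases, lost the call in 12 and gained it in 2, both for CD74 (replicate block, adjusted p = 0.0217, and without NETs replicate 2, 0.0441), and lists did so in 245, 25 and 8. The 67 example genes lost the call in 24 cases, gained it in 7 and turned in 2. Under the replicate block MCM2 and TIMP1 gained it, both upward, at limma adjusted p of 0.0318 and 0.00539. Tests on recovered whole reads were planned and not run, since reads could not be recovered, and without counts the depth behind a low value stays unknown.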

Other observations

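Of the tests below, those of the scaling of all calls, the scaling of the ribosomal list, MT2A reads and PF4V1 reads were chosen after the result was seen. Outside the fixed lists 1390 genes rose and 2697 fell with no overlap between groups, and those named next were chosen after their values were seen. The complement component C3 rose from 5.60 to 99.2 RPKM (log2 fold change 4.04 ± 0.11 SE, limma adjusted p = 1.04e-10), and the decoy receptor for RANKL, TNFRSF11B, from 40.5 to 438 RPKM (3.42 ± 0.11). The crosslinking enzyme TGM2 rose from 8.07 to 110.3 RPKM, the hormone STC1 from 1.5 to 119.8 RPKM, WNT5A from 9.86 to 85.9 RPKM and the glucocorticoid-activating enzyme HSD11B1 from 3.0 to 37.8 RPKM. The zinc importers SLC39A14 and SLC39A8 rose from 21.7 to 176 RPKM and from 1.61 to 19.5 RPKM. The thrombin receptor F2R fell from 25.3 to 3.26 RPKM, thrombomodulin (THBD) from 38.3 to 5.39 RPKM and the small heat shock protein HSPB6 from 433 to 82.8 RPKM.

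By the deposited annotation, 36 of 63 tested cytokine genes rose, 57.1% against 13.7% of all tested genes (Fisher's exact test, adjusted p = 8.96e-15 over 40 tests). Growth factor genes went both ways, with 22 of 57 higher (adjusted p = 1.12e-05) and 21 lower by the same exact test (adjusted p = 0.0829). Among 648 genes of extracellular products 178 rose and 217 fell (exact test, adjusted p = 7.90e-20 and 3.32e-06), and among 88 translation regulators 3 rose (exact test, adjusted p = 0.00700). These tests take genes as independent, which they are not. The filter also admits genes that are above it only with NETs and leaves out those that stayed low. This favours rises in classes with many genes near 0 without NETs, cytokines among them.

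PF4 and PF4V1, chemokines known from platelets, rose with NETs, PF4V1 from 0.195 to 52.9 RPKM (log2 fold change 6.26 ± 0.11 SE) and PF4 from 0.0486 to 6.81 RPKM (3.73 ± 0.15 SE, limma adjusted p = 2.38e-09). Platelet RNA brought with the NETs was argued against, since the median difference over 13 other platelet markers was 0 RPKM. The highest of them with NETs was ITGB3, which fibroblasts also express and which rose from 7.17 to 12.6 RPKM. Transcription running on through the whole chemokine cluster was argued against too, since 75% of the 12 genes examined were higher in both NETs libraries and PPBP, between PF4 and CXCL5, stood at 0.00684 RPKM. The genes not higher included RASSF6, which lies outside the cluster, and 7 annotated genes inside it had no deposited values. Running on from a direct neighbour was not tested, and PF4V1 lies between CXCL6 and CXCL1, which both rose. Reads of PF4V1 counted for PF4 cannot be told apart from PF4 reads, because PF4 lay at 13.0% of PF4V1 and the genes are near-identical. No biological explanation was tested.

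More genes were called lower than higher, ribosomal protein genes among them. Under median of ratios scaling 49.0% of calls were higher, but that scaling centres the typical gene, so scaling to a library total cannot be told apart from a true excess of falls. For the ribosomal list, a scaling shift of the size estimated was argued against as the whole cause. Median of ratios scaling moved the median log2 fold change of all tested genes by 0.09 and that of the list from -0.46 to -0.37. It acts on all genes nearly alike, so this result followed from the size of the shift. A trend with transcript length was argued against too, since fold changes barely followed length (rho = 0.00438 across genes). After removal of that trend the ribosomal median was -0.43, relative to genes of like length. The -0.46 is not relative in this way, since the median of all tested genes on the deposited scale was -0.09. The SE of both medians, 0.03, is over the list's genes, which had an estimated correlation of 0.74. It does not measure the spread between libraries. Between the no agent replicates, log2 differences correlated with transcript length across genes at rho = -0.545 (-0.127 between the NETs replicates) and the ribosomal median differed by 0.24, so a difference between libraries stays open for part of the fall.

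Metallothionein genes rose with NETs, with log2 fold changes from 1.22 for MT1A to 5.58 for MT1F among the members called, MT1A losing its call without the filter on low values (limma adjusted p = 0.211). A metal reaching the cells with the NETs or the medium may be a cause, since the zinc exporter SLC30A1, which the metal-responsive factor MTF1 induces, rose by 0.85 on the log2 scale (limma adjusted p = 3.88e-04), though without the filter it was not called (0.0581). The zinc importers SLC39A14 and SLC39A8 rose too, by 2.99 and 3.24. SLC30A1 therefore cannot tell added metal from a larger uptake of zinc by the cells. Reads of the abundant MT2A counted for MT1F and MT1G were argued against, since the median of these rose by 2.06 (SE 0.22) more than MT2A. For the 5 other called members, with a median difference of -0.70 (SE 0.23), MT2A reads cannot be told apart from a rise of their own, since a smaller rise follows from both. An acute-phase response stays open, because 3 of 10 tested acute-phase genes rose, 30% against 13.7% of other genes (Fisher's exact test, p = 0.147), while 2 fell and 17 of the 27 listed were under the filter, too few to decide, and the list was drawn outside those already seen and so lacks C3, LBP and SERPINA1, which rose, while cytokine signalling was not separated from metal.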
